A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

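The series held 16 two-colour expression arrays of yeast in the W303 background, wild type or carrying the esa1-L254P allele of the acetyltransferase gene of NuA4. Cells were arrested in G1 with alpha factor for 1 h, or arrested for 2 h and released into S phase, and were left untreated or exposed to 0.05% methyl methanesulfonate (MMS) for 1 h. PolyA RNA was labelled by oligo-dT priming. The 8 comparisons (MMS over untreated in each strain and phase, esa1-L254P over wild type in each phase and treatment) each had 2 arrays with the dyes exchanged: in replicate 1 the test RNA carried Cy5, in replicate 2 it carried Cy3. The values used were the log2 ratios deposited by the authors. The base of the logarithm was not stated and was taken as 2, the default of limma. The ratio was taken as Cy5 over Cy3 and the second array of each comparison was turned, so that positive values mean higher in MMS or in esa1-L254P. Per the submitters' processing notes, R 3.1.1 and limma 3.0 were used; background correction and within-array normalization were not given in the sources used here, and neither was whether the 2 arrays of a comparison shared an RNA preparation. Column medians of the 16 arrays lay between -0.0058 and 0.0048, and no scaling between arrays was applied.

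All work used R 4.3.3 with limma 3.58.1. The value tables had 15744 spots, none missing, with values from -4.6938 to 5.6560. Their order did not match the probe numbers of the platform table: read by number, duplicate spots of a gene correlated at -0.0302 to 0.0257. The order was therefore searched. Of 15552 systematic orderings scored on 2035 genes by the agreement of duplicate spots, the chosen one scored 1.1235, the next 0.0477, and the best after shuffling 0.0437. The score was the mean product of the standardized, capped values of both spots, which unlike a correlation can exceed 1. In the other 2035 genes, which took no part in the search, duplicate spots then correlated at 0.677 to 0.948 (median 0.913). The search used only which spots share a gene, never the direction of a change, but every gene name below rests on it. Of the spots, 8152 carried 1 gene symbol and 7592 carried none and were not used. Spots of a gene were averaged, giving 4073 genes, 4070 with 2 spots and 3 with 4. Of the symbols, 3940 were current, 125 were updated and 8 were kept as given. The R64 gene table served only for names, lengths and chromosome membership. Between 1 and 55 genes per comparison had spots more than 0.5 apart.

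The exchange of the dyes was checked before the tests. Untransformed, the 2 arrays of a comparison correlated negatively across genes in 6 of 8 comparisons (-0.697, -0.716, -0.462, -0.496, -0.163 and -0.290), as exchanged dyes require. The exceptions were esa1-L254P over wild type with MMS, at 0.215 in G1 and 0.612 in S, where the dye effect was larger than the difference compared. These correlations cannot tell Cy5 over Cy3 from Cy3 over Cy5, so the sign rests on the assumption above. With that sign MAG1, of the damage-inducible list, rose in every MMS comparison (0.86 to 1.12), and RNR3 and HUG1 rose in S but not in G1. A direct fit of the dye term called 2159 of 4073 genes. Its median over cytosolic ribosomal protein genes was 1.02, with 133 of 135 called. Deviations from the comparison means of arrays with the same replicate number correlated at 0.619 to 0.892 (median 0.792, 28 pairs of comparisons), so the replicate number, which is also the dye orientation, was taken as a block in an alternative fit.

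Before the data were examined, the following were fixed: the comparisons, the median centring, the averaging of spots, 23 gene lists from general knowledge of yeast, the tests, the threshold and most alternatives. One limma model covered all 16 arrays with 1 coefficient per comparison and no dye term, with 8 residual degrees of freedom and a prior of 1.744 degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The median standard error was 0.149, against 0.093 with the replicate as a block (7 residual degrees of freedom), which leaves the fold changes unchanged. The strain difference of the MMS response was estimated in each phase as the mean of both ways to form it, over 8 arrays. Pooled fits of 2 against 2 comparisons, or 4 against 4 arrays, asked for differences by phase, by strain and by MMS. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with the correlation estimated from the arrays. Lists of ergosterol biosynthesis, mitochondrially encoded genes, other HIS genes and other ADE genes were added after the values were seen, as were the tests of the difference between phases within 1 strain or treatment.

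Genes are named by rule. ESA1, REV1, REV3, REV7, RAD30, RNR1 to RNR4, HUG1 and MAG1 are given in every comparison. Up to 8 genes per direction are given by size of change among the called genes whose arrays both lay on the same side, and up to 4 members per list by smallest p together with called members of opposite direction. List members without a matching symbol on the arrays are not reported here. Standard errors and p-values are those of limma and measure only the spread between these arrays, which may be technical; the 2 arrays per comparison limit precision.

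The model was tested on simulated data with the noise of these arrays and 200 changed genes of 4073. The simulated noise was independent between arrays. Differences between cultures that several arrays may share were not simulated, so the false calls below do not cover them. In the comparison of MMS in wild type in G1 it recovered 40.3%, 74.6% and 90.9% of genes changed by 0.5, 1 and 2 log2 units with 0 false calls. The block recovered 74.6%, 92.5% and 100% with 7 false calls, and averaging the 2 arrays of each comparison to 1 value recovered 58.2%, 85.1% and 97.0% with 9. For the averaged fit the change was also simulated, with opposite sign, in the strain comparison of G1 with MMS. Its recovery is therefore not directly comparable with the others. For the strain difference of the MMS response in G1 the model recovered 49.3%, 88.1% and 90.9% with 2 false calls. For the response by phase it recovered 37.3%, 62.7% and 90.9% with 0. Alternatives tried were the block, the 2 arrays of a comparison averaged (3 RNA differences per phase, 2 residual degrees of freedom), each way to the strain difference alone, no centring, scaling of arrays, no filter, each spot on its own, the 8 arrays of a phase alone, leaving out each array, and a correction for coding length. In the pooled fits averaging left fewer residual degrees of freedom. The length correction was chosen after the data were seen and used 4048 genes, 99.4% of the total.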

Results

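The data were 16 two-colour arrays of yeast messenger RNA, forming 8 direct comparisons of 2 dye-swapped arrays each. Wild type and esa1-L254P cells in G1 or S phase were compared with and without the alkylating agent MMS (4 comparisons), and the strains were compared with each other in each phase and treatment (4 comparisons). Changes below are log2 ratios over 2 arrays, given with a standard error where one follows the ± sign, and were tested with limma over 4073 genes.

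ESA1 encodes the catalytic subunit of NuA4, and the mutant carries a point allele, so its transcript level does not check the strain labels. ESA1 was higher in esa1-L254P than in wild type in untreated G1 cells (0.66 ± 0.07, adjusted p = 0.000654). The difference did not pass in untreated S cells (0.11, adjusted p = 0.337), in G1 with MMS (0.24, adjusted p = 0.0634, with the replicate as a block 0.0165) or in S with MMS (0.34, adjusted p = 0.155, with the block 0.0249). With MMS it rose in wild-type G1 (0.33, adjusted p = 0.00496), fell in wild-type S (-0.36, adjusted p = 0.00307) and in esa1-L254P G1 (-0.22, adjusted p = 0.0469), and did not pass in esa1-L254P S (-0.03, adjusted p = 0.773).

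The first question was what wild-type cells arrested in G1 do after an hour in MMS. The sulfite exporter SSU1 rose most (2.40 ± 0.69, adjusted p = 0.0213), followed by the polyubiquitin gene UBI4 (2.19 ± 0.54, adjusted p = 0.0108), SLF1 (1.89 ± 0.26), RPN8 (1.71 ± 0.38), GRE2 (1.69 ± 0.42), FRM2 (1.62 ± 0.18), TIS11 (1.62 ± 0.10) and BTN2 (1.57 ± 0.10). The largest decreases were PTR2 at -2.90 ± 0.27, PHO3 at -2.85 ± 0.26, NDE1 at -2.52 ± 0.31, PUT4 at -2.50 ± 0.12, PHO5 at -2.25 ± 0.42, SCM4 at -2.25 ± 0.22, CYC1 at -2.24 ± 0.48 and HXT4 at -2.11 ± 0.13. MAG1, the glycosylase that removes methylated bases, rose by 1.05 ± 0.16 (adjusted p = 0.000875). The ribonucleotide reductase genes did not rise: RNR1 fell by 1.23 ± 0.32 (adjusted p = 0.0132) and RNR3 by 0.25 ± 0.08 (adjusted p = 0.0316), while RNR2 (-0.53), RNR4 (-0.02) and HUG1 (0.01) did not pass. Of the translesion polymerase genes none passed, REV1 at -0.01, REV3 at 0.28 (adjusted p = 0.234, with the block 0.00557), REV7 at 0.08 and RAD30 at 0.32 (adjusted p = 0.291, with the block 0.00195).

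Among the proteasome genes of this comparison, 16 of 35 rose (19 adjusted over the list alone, 28 with the block) and none fell, with a median of 0.98; RPN5 (1.33), RPT3 (1.21) and RPN4 (0.66), which encodes their activator, were examples. The list passed (adjusted p = 7.38e-06) but not with the correlation between genes estimated from the arrays (adjusted p = 0.562 with an estimated correlation). Excision and alkylation repair had 9 of 22 members up (10 adjusted over the list alone), among them RAD27 (0.62), RAD26 (0.75) and RAD2 (0.98), while OGG1 fell (-0.52); adjusted p was 0.00785, or adjusted p = 0.29 with an estimated correlation. In homologous recombination 10 of 18 rose (10 adjusted over the list alone), including RAD50 (0.68), MUS81 (0.67), RAD59 (0.83) and SGS1 (0.42). As a list they had adjusted p = 0.00124, and adjusted p = 0.219 with an estimated correlation. General stress and chaperone genes had 13 of 30 up (14 adjusted over the list alone), for example HSP12 (0.98), HSP42 (1.29) and HSP78 (1.01), against CTT1 (-0.55). Tested together they had adjusted p = 0.0111, and adjusted p = 0.29 with an estimated correlation. Of the Yap1 targets, 6 of 19 rose (6 adjusted over the list alone, 11 with the block), including OYE3 (0.70), LOT6 (0.56), GSH1 (0.64) and GPX2 (1.53). Their list had adjusted p = 0.00605, and adjusted p = 0.461 with an estimated correlation. Ribosome biogenesis fell in 22 of 48 members (24 adjusted over the list alone), as UTP10 (-1.02), RRP12 (-0.87), ERB1 (-0.82) and RRP5 (-0.65) show, against EBP2 (0.38). With camera the list had adjusted p = 4.67e-05, and adjusted p = 0.29 with an estimated correlation. Respiratory chain and ATP synthase genes fell in 15 of 34 cases (15 adjusted over the list alone), with INH1 at -1.50, QCR2 at -1.40, SDH1 at -1.30 and CYT1 at -1.84. For the list, camera gave adjusted p = 0.000232, and adjusted p = 0.562 with an estimated correlation. M/G1 genes fell in 11 of 23 cases (14 adjusted over the list alone), among them MCM3 (-0.87), EGT2 (-0.67), SCW11 (-0.78) and TEC1 (-0.60), while DSE1 (0.72) and RME1 (0.66) rose. In camera the group had adjusted p = 0.00809, and adjusted p = 0.299 with an estimated correlation. The damage-inducible list had 6 of 17 up and 2 down (7 and 3 adjusted over the list alone) and did not pass (adjusted p = 0.131), with PHR1 (0.62), DUN1 (0.66) and DDI1 (0.96) up. Translesion synthesis and post-replication repair, with POL32 up (0.36) and SIZ1 down (-0.57), did not pass (adjusted p = 0.5), nor did cytosolic ribosomal proteins (adjusted p = 0.418, with the block 0.0382) or glycolysis (adjusted p = 0.384, with the block 0.0438). With the block and an estimated correlation these stood at 0.817 and 0.698. Histones (adjusted p = 0.384), with CSE4 up (1.02), and diploid, meiotic and sporulation genes (adjusted p = 0.0869) also did not pass. In all, 737 genes rose and 729 fell, 73 and 137 of them at least 2-fold, and 1108 and 1184 were called with the block. Without replicate 1 there were 592 calls and without replicate 2 there were 873.

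In wild-type cells released into S phase, where MMS blocks replication forks, both damage-inducible and cell cycle genes changed. No measure of cell cycle position was used here. In the S comparisons of either strain, a difference in position between treated and untreated cells could not be told apart from a response of these genes to damage. RNR3 rose by 1.24 ± 0.08 (adjusted p = 9.43e-06), RNR4 by 1.36 ± 0.22 (adjusted p = 0.00092), RNR2 by 1.54 ± 0.44 (adjusted p = 0.0202), RNR1 by 1.30 ± 0.32 (adjusted p = 0.00945), HUG1 by 1.06 ± 0.15 (adjusted p = 0.000429) and MAG1 by 1.12 ± 0.16 (adjusted p = 0.000542). The largest increases were AHP1 at 4.04 ± 1.10, TRX2 at 2.96 ± 0.94, SSU1 at 2.84 ± 0.69, ARG1 at 2.83 ± 0.75, TSA1 at 2.36 ± 0.78, LYS20 at 2.31 ± 0.72, LYS1 at 2.07 ± 0.45 and UBI4 at 1.92 ± 0.54. Among the 8 largest decreases were the mitotic genes SWI5 by 2.78 ± 0.20, SPO12 by 2.40 ± 0.14, HOF1 by 2.11 ± 0.11 and CLB2 by 2.07 ± 0.15, next to ERG11 (-2.32 ± 0.50), PTR2 (-2.25 ± 0.27), PHO11 (-2.22 ± 0.65) and PHO3 (-2.12 ± 0.26). The translesion genes REV1 (-1.20 ± 0.18, adjusted p = 0.00066) and REV7 (-0.36, adjusted p = 0.0158) fell, while REV3 (-0.35, adjusted p = 0.126, with the block 0.0013) and RAD30 (-0.05, adjusted p = 0.878) did not pass.

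All 19 genes of the G2/M CLB2 cluster fell in this comparison (19 adjusted over the list alone), with a median of -1.64, MYO1 at -1.66 and CDC20 at -1.37 (adjusted p = 1.02e-14). G1/S genes rose in 21 of 31 cases (22 adjusted over the list alone), among them CLB6 (0.87), MSH6 (0.94), RAD27 (1.02) and RFA1 (1.32), with adjusted p = 2.74e-09. Of the damage-inducible list 14 of 17 rose (14 adjusted over the list alone), including DIN7 (0.78), with a median of 1.06 and adjusted p = 1.45e-06. Ribosome biogenesis fell in 40 of 48 cases (42 adjusted over the list alone), with EBP2 down by 1.29, RRP5 down by 1.27, MAK16 down by 1.26 and DIP2 down by 1.00 (adjusted p = 7.7e-16). General stress genes rose in 16 of 30 cases (17 adjusted over the list alone), with GRE3 at 1.41, TFS1 at 1.44, XBP1 at 1.13 and ALD3 at 0.64 (adjusted p = 1.99e-06). These 5 lists also passed with the correlation estimated. With the block and the correlation estimated, the damage-inducible and G1/S lists passed (adjusted p = 0.011 each) and the CLB2 cluster, ribosome biogenesis and general stress lists did not (adjusted p = 0.122 each). Yap1 targets rose in 14 of 19 cases (14 adjusted over the list alone), with OYE3 at 0.86, GTT2 at 1.35 and AAD4 at 0.81. The group as such had adjusted p = 1.86e-06, and adjusted p = 0.133 with an estimated correlation. Gcn4 targets rose in 10 of 33 cases (5 adjusted over the list alone, 23 with the block), with LYS1 as above, SER3 at 1.08 and ARG8 at 0.86. Together these genes had adjusted p = 0.000203, and adjusted p = 0.514 with an estimated correlation. Iron genes rose in 8 of 19 cases (8 adjusted over the list alone), with TIS11 at 1.56, FIT3 at 1.03, ARN1 at 0.79 and ARN2 at 1.23, while HMX1 fell by 1.00. As a list they had adjusted p = 0.00484, and adjusted p = 0.0609 with an estimated correlation. Excision and alkylation repair rose in 8 of 22 cases, RAD16 by 0.80 and OGG1 by 0.45 among them, while RAD3 fell by 0.38 (9 adjusted over the list alone; adjusted p = 0.0417, adjusted p = 0.258 with an estimated correlation). The proteasome rose in 8 of 35 (4 adjusted over the list alone, 15 with the block). The proteasome list had adjusted p = 0.000676, and adjusted p = 0.559 with an estimated correlation. Respiratory genes fell in 13 of 34 cases (13 adjusted over the list alone, 20 with the block). Their list had adjusted p = 0.000676, and adjusted p = 0.514 with an estimated correlation. Cytosolic ribosomal protein genes had a median of -0.79 with 2 of 135 down (0 adjusted over the list alone, 102 with the block). With camera the list had adjusted p = 0.00811, and adjusted p = 0.935 with an estimated correlation. The translesion and post-replication list did not pass (adjusted p = 0.876); POL31 (0.47), UBC13 (0.82), POL32 (0.43) and POL30 (1.52) rose. The checkpoint list did not pass either (adjusted p = 0.924), with RAD53 (1.16), DUN1 (0.73) and TOF1 (0.47) up and RAD9 (-0.79) down. NuA4 subunits did not pass as a list (adjusted p = 0.052), although EAF6 (-0.57), TRA1 (-0.63) and EPL1 (-0.75) fell and EAF3 (0.56) rose. In all, 779 genes rose and 781 fell, 122 and 129 of them at least 2-fold (1140 and 1236 with the block; 803 in total without replicate 1 and 728 without replicate 2).

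**Figure D1:**
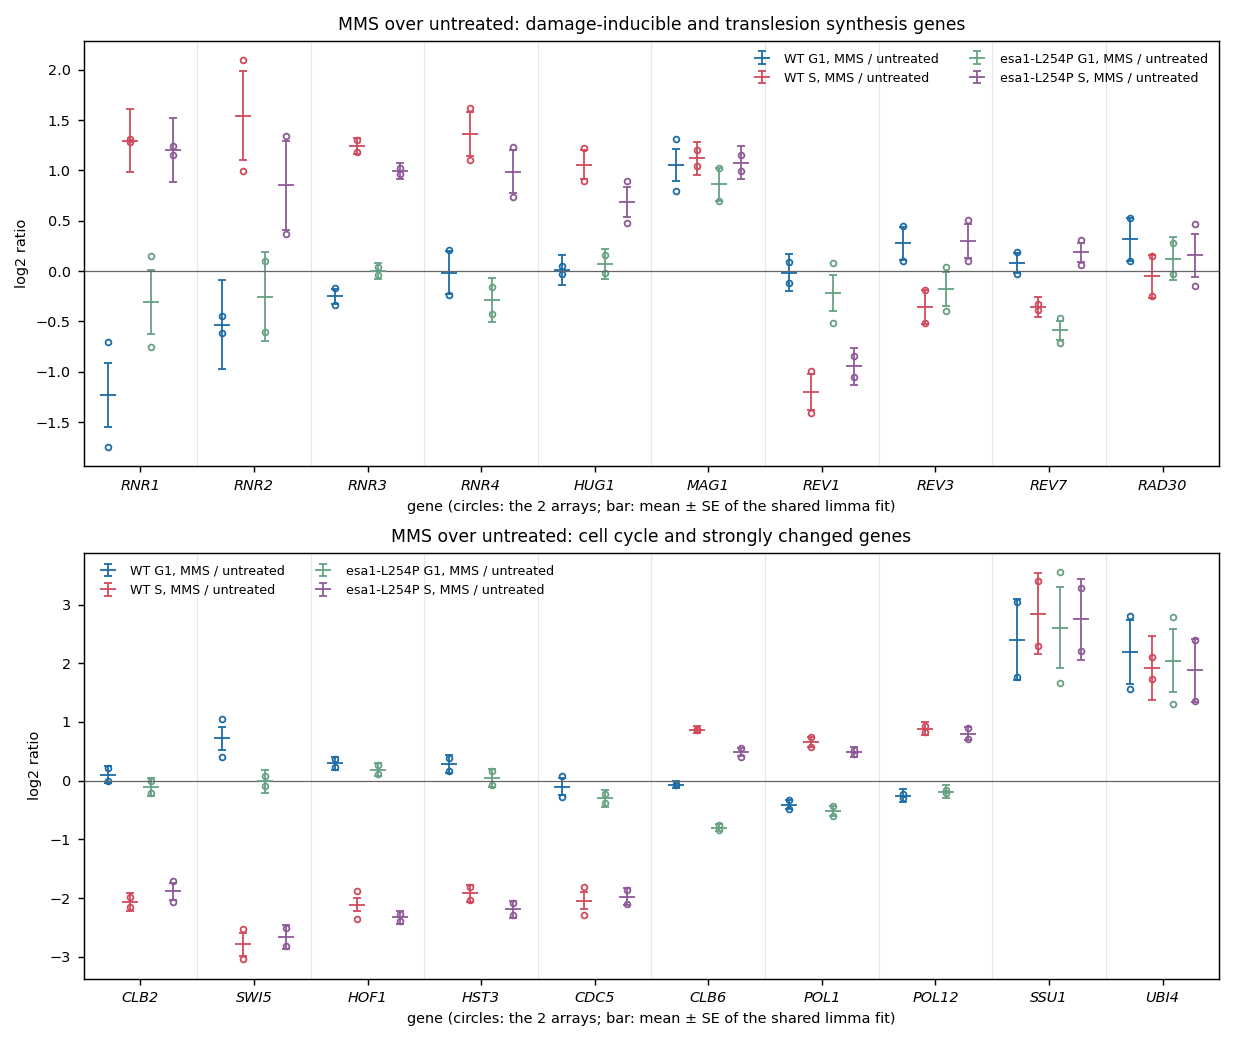
Log2 ratios of MMS over untreated cells for damage-inducible, translesion synthesis, cell cycle and strongly changed genes in each strain and phase. Circles are the 2 arrays, bars the mean ± standard error; CLB2 stood at -2.07 in wild-type S.

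The same treatment was then asked of esa1-L254P in G1. SSU1 (2.61 ± 0.69), GRE2 (2.13 ± 0.42), UBI4 (2.05 ± 0.54), FRM2 (2.01 ± 0.18), TIS11 (1.83 ± 0.10), ERO1 (1.76 ± 0.43), GPX2 (1.71 ± 0.40) and AAD6 (1.55 ± 0.31) rose most. The largest decreases included ERG3 at -2.56 ± 0.52, CYB5 at -2.44 ± 0.49, ERG2 at -2.30 ± 0.65, ERG5 at -2.20 ± 0.39, OLE1 at -1.96 ± 0.42 and ERG11 at -1.94 ± 0.50, next to NDE1 (-2.24 ± 0.31) and PHO3 (-1.91 ± 0.26). MAG1 rose by 0.86 ± 0.16 (adjusted p = 0.00397), whereas RNR1 (-0.30), RNR2 (-0.26), RNR3 (0.00), RNR4 (-0.29) and HUG1 (0.07) did not pass. REV7 fell by 0.59 (adjusted p = 0.00205), and REV1 (-0.22), REV3 (-0.18, adjusted p = 0.473, with the block 0.0457) and RAD30 (0.12) did not pass.

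General stress genes rose in 19 of 30 cases in this comparison (21 adjusted over the list alone), including ALD3 (1.07), PGM2 (1.00), XBP1 (0.84) and GLC3 (0.94), and the list passed both with the preset correlation (adjusted p = 6.77e-09) and with the correlation estimated (adjusted p = 0.0263), but not with the block and the correlation estimated (adjusted p = 0.215). Ribosome biogenesis fell in 35 of 48 cases (37 adjusted over the list alone), with EBP2 at -1.03, MAK16 at -1.11, RRP5 at -0.69 and DIP2 at -0.60. For the list, camera gave adjusted p = 1.04e-14, and adjusted p = 0.0591 with an estimated correlation. Iron genes rose in 9 of 19 cases, ARN1 by 0.90 and SIT1 by 0.95, while HMX1 fell by 1.51 (9 adjusted over the list alone; adjusted p = 0.00126, adjusted p = 0.0602 with an estimated correlation). Yap1 targets rose in 9 of 19 cases, among them OYE3 (0.86) and GSH1 (0.81) (11 adjusted over the list alone, 16 with the block). The Yap1 list had adjusted p = 1.91e-05, and adjusted p = 0.226 with an estimated correlation. Proteasome genes rose in 13 of 35 cases, RPT3 by 1.22 and RPN10 by 0.61 (13 adjusted over the list alone, 22 with the block). The group as such had adjusted p = 1.71e-06, and adjusted p = 0.558 with an estimated correlation. Respiratory genes fell in 18 of 34 cases (19 adjusted over the list alone), CYC7 by 0.85, INH1 by 1.34, CYT1 by 1.27 and QCR6 by 1.39. Together these genes had adjusted p = 6.16e-08, and adjusted p = 0.375 with an estimated correlation. Homologous recombination rose in 5 of 18 cases (5 adjusted over the list alone, 9 with the block), with RAD52 at 0.83 and RAD59 at 0.78. As a list they had adjusted p = 0.01, and adjusted p = 0.179 with an estimated correlation. G1/S genes fell in 11 of 31 cases (11 adjusted over the list alone), with CLB6 at -0.80, PCL1 at -0.76 and POL1 at -0.52, while RFA1 rose (0.87). Tested together they had adjusted p = 0.00719, and adjusted p = 0.226 with an estimated correlation. Gcn4 targets had 2 of 33 up (1 adjusted over the list alone, 11 with the block; adjusted p = 0.00758, adjusted p = 0.863 with an estimated correlation). Ribosomal protein genes had a median of -1.40 with 2 of 135 down (0 adjusted over the list alone, 132 with the block). Their list had adjusted p = 7.6e-07, and adjusted p = 0.863 with an estimated correlation. The damage-inducible (adjusted p = 0.109), excision repair (adjusted p = 0.71), translesion (adjusted p = 0.539) and checkpoint (adjusted p = 0.871) lists did not pass. In all, 542 genes rose and 566 fell, 45 and 70 of them at least 2-fold (986 and 1104 with the block; 549 in total without replicate 1 and 407 without replicate 2).

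In esa1-L254P cells in S phase, RNR3 (0.99 ± 0.08, adjusted p = 2.96e-05), RNR1 (1.20 ± 0.32, adjusted p = 0.0158), RNR4 (0.99 ± 0.22, adjusted p = 0.00653), HUG1 (0.69 ± 0.15, adjusted p = 0.00593) and MAG1 (1.08 ± 0.16, adjusted p = 0.000895) rose with MMS. RNR2 did not pass (0.85 ± 0.44, adjusted p = 0.174, with the block 0.0163). The largest increases were SSU1 (2.75 ± 0.69), ARG1 (2.56 ± 0.75), LYS20 (2.09 ± 0.72), LYS1 (1.89 ± 0.45), UBI4 (1.88 ± 0.54), GRE2 (1.86 ± 0.42), the autophagy kinase gene ATG1 (1.82 ± 0.17) and SLF1 (1.74 ± 0.26). ERG3 (-3.14 ± 0.52), ERG11 (-3.11 ± 0.50), SWI5 (-2.66 ± 0.20), DBP2 (-2.35 ± 0.37), HOF1 (-2.33 ± 0.11), NDE1 (-2.33 ± 0.31), SUR7 (-2.30 ± 0.30) and ATF2 (-2.29 ± 0.13) fell most. REV1 fell by 0.95 ± 0.18 (adjusted p = 0.00314), while REV3 (0.30, adjusted p = 0.201, with the block 0.00348), REV7 (0.19) and RAD30 (0.16) did not pass.

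All 19 CLB2 cluster genes fell (19 adjusted over the list alone), with HST3 at -2.19, BUD4 at -1.71 and MYO1 at -1.14 (adjusted p = 1.3e-15). Of the damage-inducible list, 14 of 17 rose (14 adjusted over the list alone), with DUN1 at 0.77 and MSN4 at 0.57 (adjusted p = 8.84e-07). Ribosome biogenesis fell in 39 of 48 cases (41 adjusted over the list alone), with RRP5 at -0.86, RRP12 at -0.86, EBP2 at -0.80 and DIP2 at -0.71 (adjusted p = 1.7e-14). General stress genes rose in 18 of 30 cases (19 adjusted over the list alone), with XBP1 at 1.02, GLC3 at 0.98, TFS1 at 0.96 and ALD3 at 0.73 (adjusted p = 8.84e-07). These 4 lists passed with the correlation estimated as well. With the block and the correlation estimated, the damage-inducible list passed (adjusted p = 0.0159) and the CLB2 cluster, ribosome biogenesis and general stress lists did not (adjusted p = 0.131 each). Iron genes rose in 4 of 19 cases and fell in 5 (FET3 by 1.33, HMX1 by 1.11, FTR1 by 0.78, CCC2 by 0.33 and FRE2 by 0.28), and the list did not pass (4 and 5 adjusted over the list alone; adjusted p = 0.573). G1/S genes rose in 18 of 31 cases (19 adjusted over the list alone), with MSH6 at 0.87, RAD27 at 0.76 and SMC3 at 0.59, while YOX1 (-0.60) and GIC1 (-0.67) fell. With camera the list had adjusted p = 2.82e-05, and adjusted p = 0.051 with an estimated correlation. Excision repair rose in 8 of 22 cases (8 adjusted over the list alone, 13 with the block), with NTG1 at 0.51, RAD16 at 0.71 and RAD2 at 0.99. For the list, camera gave adjusted p = 0.001, and adjusted p = 0.0978 with an estimated correlation. Homologous recombination rose in 6 of 18 cases, MUS81 by 0.53 and RDH54 by 0.71 (6 adjusted over the list alone, 12 with the block; adjusted p = 0.00772, adjusted p = 0.0989 with an estimated correlation). Yap1 targets rose in 12 of 19 cases (13 adjusted over the list alone), with OYE3 at 0.79, LOT6 at 0.64 and FLR1 at 1.43. In camera the group had adjusted p = 5.03e-06, and adjusted p = 0.138 with an estimated correlation. The proteasome rose in 13 of 35 cases (17 adjusted over the list alone, 25 with the block), with RPT3 at 1.42, RPN6 at 1.39, RPT5 at 1.11 and RPN10 at 0.78. The group as such had adjusted p = 1.18e-06, and adjusted p = 0.452 with an estimated correlation. Gcn4 targets rose in 10 of 33 cases (2 adjusted over the list alone, 21 with the block; adjusted p = 0.000614, adjusted p = 0.592 with an estimated correlation), and respiratory genes fell in 11 of 34 (11 adjusted over the list alone, 20 with the block). The respiratory list had adjusted p = 7.79e-05, and adjusted p = 0.452 with an estimated correlation. Genes of the phosphate list fell in 5 of 16 cases (6 adjusted over the list alone, 10 with the block), with PHM6 at -1.11, PHO12 at -1.69, PHO5 at -1.56 and PHO11 at -2.23, while PHO8 rose (0.44). As a list they had adjusted p = 0.0472, and adjusted p = 0.411 with an estimated correlation. M/G1 genes fell in 10 of 23 cases, AMN1 by 1.04 and MCM7 by 0.89, while RME1 (0.89) and MCM5 (0.34) rose (10 adjusted over the list alone; adjusted p = 0.0322, with the block 0.0691, adjusted p = 0.411 with an estimated correlation). Ribosomal protein genes had a median of -0.96 with 4 of 135 down (1 adjusted over the list alone, 124 with the block). Tested together they had adjusted p = 0.00122, and adjusted p = 0.785 with an estimated correlation. The translesion list did not pass (adjusted p = 0.18), nor did mating pheromone response (adjusted p = 0.392). In all, 664 genes rose and 684 fell, 70 and 107 of them at least 2-fold (1030 and 1238 with the block; 821 in total without replicate 1 and 682 without replicate 2).

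**Figure D2:**
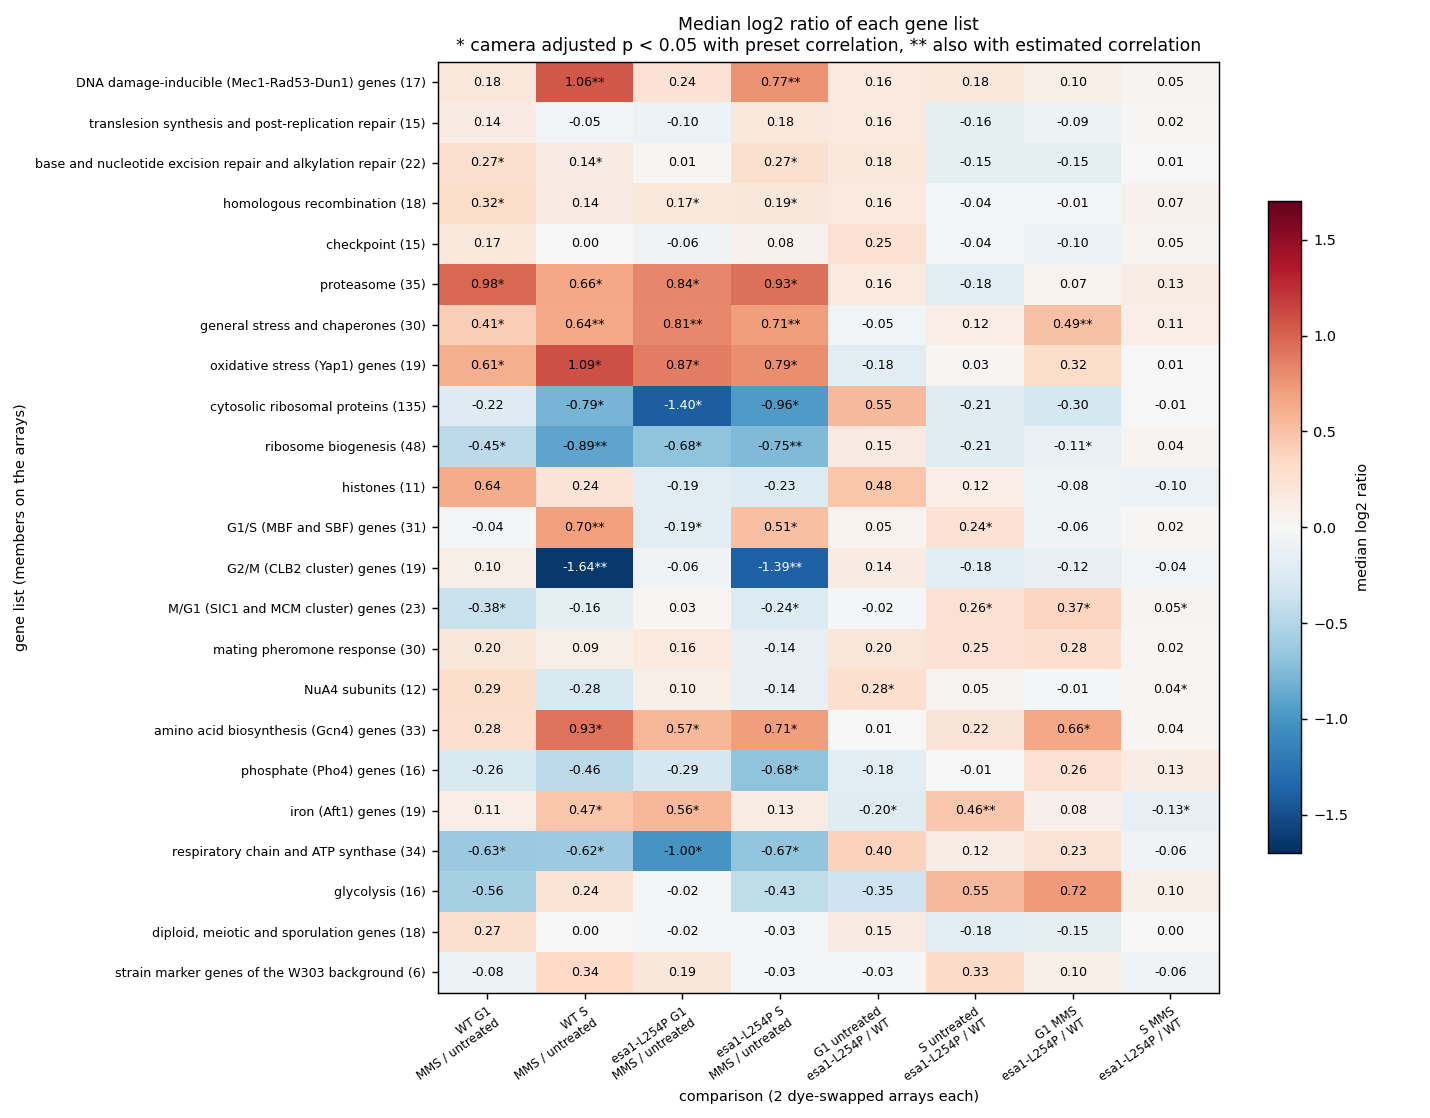
Median log2 ratio of each gene list fixed beforehand (number of members on the arrays in brackets) in the 8 comparisons. Stars mark lists that passed with camera at the preset correlation, and doubled stars those that also passed with the correlation estimated; the CLB2 cluster reached -1.64 in wild-type S.

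How the MMS responses relate was asked across genes, which are not independent replicates. The response of wild type and that of esa1-L254P correlated at 0.786 in S, with 432 genes up in both, 453 down in both and 34 opposite, and at 0.411 in G1, with 200, 235 and 147. Between G1 and S the responses correlated at 0.339 in wild type (216 up in both, 259 down in both, 284 opposite) and at 0.682 in esa1-L254P (306 up in both, 62 opposite). In all 4 comparisons 130 genes rose and 150 fell (249 and 301 with the block).

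The untreated strains were compared in G1 to ask what the allele changes without damage. HIS3 was lower in esa1-L254P (-1.91 ± 0.22, adjusted p = 0.000726), and ZRT1 (-1.18 ± 0.14), DED1 (-1.10 ± 0.22), IMD2 (-1.06 ± 0.20), MCD4 (-0.99 ± 0.16), BNA5 (-0.95 ± 0.18) and PPH22 (-0.95 ± 0.24) followed; DIA3 was lower by 1.00 ± 0.15. VMA10 (1.31 ± 0.27), SLF1 (1.28 ± 0.26), the ESCRT genes SNF7 (1.18 ± 0.15) and VPS20 (1.05 ± 0.12), SPO12 (1.12 ± 0.14), MRPL24 (1.06 ± 0.13), SRP21 (1.03 ± 0.18) and NOP15 (1.02 ± 0.19) were higher, as was ADE2 (0.72, adjusted p = 0.00634). RNR3 was slightly lower (-0.29, adjusted p = 0.0256). RNR1 (-0.30), RNR2 (-0.21), RNR4 (0.37), HUG1 (-0.17), MAG1 (0.37), REV1 (-0.01), REV3 (0.29, adjusted p = 0.265, with the block 0.00611), REV7 (0.17) and RAD30 (0.19, adjusted p = 0.607, with the block 0.0338) did not pass. NuA4 subunit genes were higher in 3 of 12 cases (5 adjusted over the list alone, 6 with the block), with YNG2 at 0.74 and EAF6 at 0.51 besides ESA1. Their list had adjusted p = 0.0326, and adjusted p = 0.19 with an estimated correlation. Iron genes were lower in 5 of 19 (5 adjusted over the list alone), with FIT1 at -0.70, FIT3 at -0.62, FRE3 at -0.57 and ARN1 at -0.44. With camera the list had adjusted p = 0.0326, and adjusted p = 0.19 with an estimated correlation. Ribosome biogenesis had 11 of 48 higher, with EBP2 at 0.83 and MAK16 at 0.81, and 3 lower, UTP10 (-0.49), NOC4 (-0.41) and UTP15 (-0.33), 13 and 3 adjusted over the list alone. The list did not pass (adjusted p = 0.124), nor did excision repair, with RAD26 (0.67) and RAD27 (0.51) up (adjusted p = 0.124), or homologous recombination (adjusted p = 0.0891, with the block 0.0335, with the block and an estimated correlation 0.729). Ribosomal protein genes had 0 of 135 called with limma at a median of 0.55 (adjusted p = 0.158), against 70 up and 4 down with the block (adjusted p = 7.75e-07, or 0.762 with the block and an estimated correlation). In all, 493 genes were higher and 379 lower (941 and 839 with the block; 293 in total without replicate 1, 175 higher and 128 lower without replicate 2).

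In untreated S cells HIS3 was again lower (-2.72 ± 0.22, adjusted p = 0.000315) and ADE2 higher (1.43 ± 0.14, adjusted p = 0.000403). Also higher in esa1-L254P were BLM3 (1.38 ± 0.28), COS10 (1.31 ± 0.25), SNO1 (1.30 ± 0.12), CTF19 (1.29 ± 0.26), PPM2 (1.27 ± 0.33), CAR2 (1.20 ± 0.15) and RGM1 (1.18 ± 0.22). Glycogen synthase GSY1 (-1.35 ± 0.07), VMA10 (-1.23 ± 0.27), HMRA1 (-1.20 ± 0.12), NRG2 (-1.11 ± 0.12), RCK1 (-1.10 ± 0.14), SPO12 (-1.08 ± 0.14) and FYV6 (-1.08 ± 0.07) were lower. The polymerase zeta genes REV7 and REV3 were lower, REV7 by 0.76 ± 0.10 (adjusted p = 0.00102) and REV3 by 0.58 ± 0.17 (adjusted p = 0.0351). REV1 (-0.46, adjusted p = 0.108, with the block 0.00535), RAD30 (-0.16), RNR1 (0.38), RNR2 (0.66), RNR3 (-0.06), RNR4 (0.43), HUG1 (-0.09) and MAG1 (-0.41) did not pass. The translesion and post-replication list as a whole, with ELG1 (-0.31) and RAD18 (-0.25) also lower, did not pass (adjusted p = 0.342). Iron genes were higher in 7 of 19 cases (10 adjusted over the list alone), with ARN1 at 0.94, FIT3 at 1.06, CCC2 at 0.51 and TIS11 at 0.51. For the list, camera gave adjusted p = 5.01e-05, and adjusted p = 0.0356 with an estimated correlation. The iron list did not pass with the block and an estimated correlation (adjusted p = 0.196). G1/S genes were higher in 7 of 31 (7 adjusted over the list alone), with YOX1 at 0.73, CLN2 at 0.85, GIC1 at 0.81 and CLB6 at 0.40. In camera the group had adjusted p = 0.0107, and adjusted p = 0.464 with an estimated correlation. M/G1 genes were higher in 8 of 23 (8 adjusted over the list alone), with SCW11 at 0.83, DSE1 at 0.83 and EGT2 at 0.56 against ASH1 (-0.75). The group as such had adjusted p = 0.03, and adjusted p = 0.802 with an estimated correlation. NuA4 subunits did not pass (adjusted p = 0.849), with EAF1 (0.87) higher and YNG2 (-0.43), EAF6 (-0.46) and YAF9 (-0.39) lower. Glycolysis, at a median of 0.55, had 0 of 16 called with limma and 7 with the block (adjusted p = 0.228, with the block 0.00927, with the block and an estimated correlation 0.859). In all, 376 genes were higher and 470 lower (757 and 852 with the block; 154 in total without replicate 1 and 205 without replicate 2). Across genes the untreated strain effects of G1 and S correlated at -0.633: of genes called in both, 8 were up in both, 12 down in both and 466 opposite. The untreated G1 strain effect also ran opposite to that of G1 with MMS (r = -0.411, with 9 up in both, 15 down in both and 180 opposite). In S the untreated effect and that with MMS had r = -0.010, with 1 up in both, 4 down in both and 0 opposite. As only 5 genes were called in S with MMS, these counts say little about agreement. With the block 25 were up in both, 15 down in both and 11 opposite. With MMS the strain effects of G1 and S correlated at 0.218, with 1 up in both, 3 down in both and 0 opposite (35, 29 and 0 with the block). The untreated G1 strain effect ran with the wild-type G1 response to MMS (r = 0.610). Here 372 genes were up in both, 253 down in both and 18 opposite. The same pair in S had r = 0.303.

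**Figure D3:**
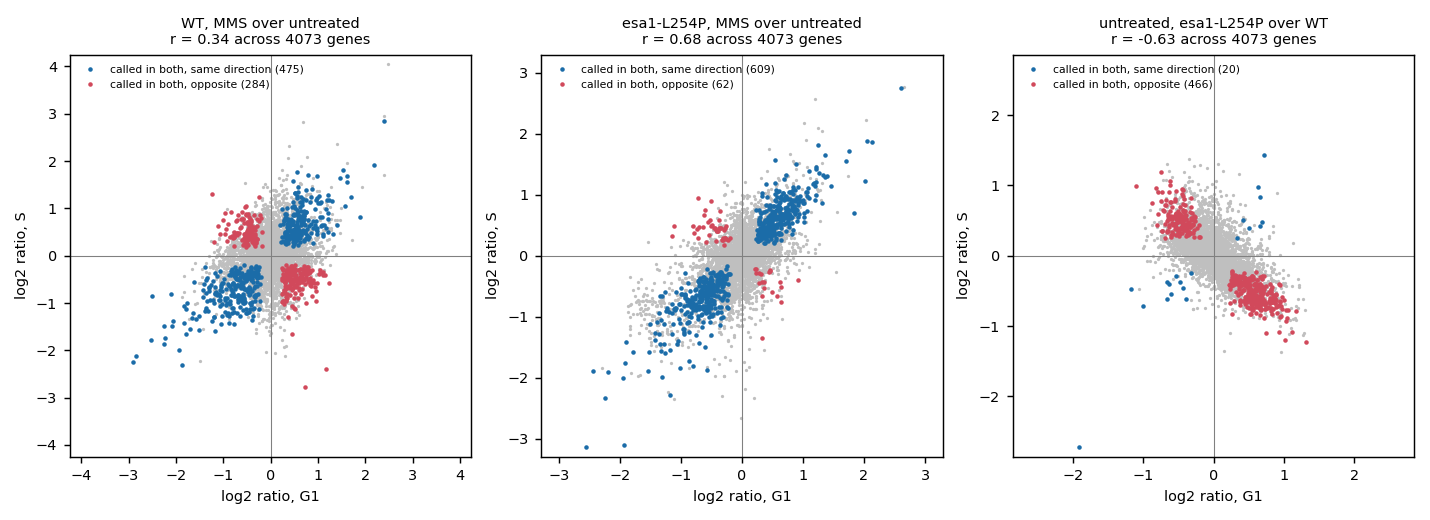
Log2 ratios in S against G1 for each of 4073 genes: MMS over untreated in wild type (r = 0.339) and in esa1-L254P (r = 0.682), and esa1-L254P over wild type without MMS (r = -0.633). Coloured points were called in both phases.

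The strains were compared directly after MMS in G1. The mitochondrial genes AI5_BETA (2.16 ± 0.51), AI5_ALPHA (2.14 ± 0.31) and OLI1 (1.83 ± 0.14) were higher in esa1-L254P, with ADE2 (1.77 ± 0.14), CTS1 (1.76 ± 0.43), GLK1 (1.51 ± 0.38), ILV6 (1.43 ± 0.40) and HXT7 (1.39 ± 0.25). HIS3 (-2.46 ± 0.22), ATG17 (-1.02 ± 0.14), DIA3 (-0.87 ± 0.15), RPC17 (-0.85 ± 0.10), LOC1 (-0.83 ± 0.19), HIT1 (-0.82 ± 0.08), FAP7 (-0.79 ± 0.09) and MED11 (-0.77 ± 0.14) were lower. REV7 was lower by 0.55 ± 0.10 (adjusted p = 0.00884); REV1 (-0.16), REV3 (-0.19), RAD30 (-0.03), RNR1 (0.14), RNR2 (0.56), RNR3 (-0.09), RNR4 (0.40), HUG1 (-0.06) and MAG1 (-0.43) did not pass. General stress genes were higher in 10 of 30 cases (12 adjusted over the list alone, 16 with the block), with DDR2 at 1.05, ALD3 at 0.67, GSY2 at 0.63 and GRE3 at 0.69. Together these genes had adjusted p = 3.11e-08, and adjusted p = 0.0301 with an estimated correlation. This call was lost with the block and an estimated correlation (adjusted p = 0.148). M/G1 genes were higher in 9 of 23 (11 adjusted over the list alone, 14 with the block), with EGT2 at 0.70, DSE4 at 0.58, DSE2 at 0.91 and DSE1 at 0.83. As a list they had adjusted p = 5.38e-08, and adjusted p = 0.0674 with an estimated correlation. Gcn4 targets had 2 of 33 up (0 adjusted over the list alone, 12 with the block; adjusted p = 1.58e-05, adjusted p = 0.691 with an estimated correlation), and ribosome biogenesis 2 of 48 down (0 adjusted over the list alone, 8 with the block). Ribosome biogenesis had adjusted p = 0.0233, and adjusted p = 0.691 with an estimated correlation. NuA4 subunits did not pass (adjusted p = 0.768), with EAF1 (0.66) and EPL1 (0.90) higher and EAF6 (-0.45) and YNG2 (-0.33) lower; the translesion list did not pass either (adjusted p = 0.134), with ELG1 lower (-0.34). Ribosomal proteins (adjusted p = 0.262, with the block 9.11e-05) and glycolysis (adjusted p = 0.0648, with the block 9.11e-05) passed only with the block, and no longer with the block and the correlation estimated (adjusted p = 0.717 each). Of the list of mitochondrially encoded genes, added after the values were seen, 8 of 17 were higher. Their list had adjusted p = 2.57e-05, and adjusted p = 0.411 with an estimated correlation. In all, 185 genes were higher and 214 lower (590 and 613 with the block, and 65 in total without replicate 1 and 154 without replicate 2). Fitting the 8 arrays of the phase alone left fewer still.

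After MMS in S the strain comparison called the fewest genes. Its 2 arrays had the lowest agreement of duplicate spots (r = 0.721 and 0.677), and 55 genes had spots more than 0.5 apart, the most of any comparison. Few calls therefore need not mean that the strains were alike. ADE2 was higher (1.44 ± 0.14, adjusted p = 0.00713), and HXT2 (-0.84 ± 0.09, adjusted p = 0.0077), SNZ3 (-0.65 ± 0.10, adjusted p = 0.0467), MAL12 (-0.49 ± 0.07, adjusted p = 0.0467) and MAL32 (-0.48 ± 0.07, adjusted p = 0.0467) were lower. TOS8 (0.56, adjusted p = 0.0824, with the block 0.0128, with pairs averaged 0.0638), EAF1 (0.47, adjusted p = 0.0873, with the block 0.00983, with pairs averaged 0.0373) and HIS3 (-1.12 ± 0.22, adjusted p = 0.112, with the block 0.0369, with pairs averaged 0.0847) did not pass. REV1 (-0.04), REV3 (0.01), REV7 (-0.11), RAD30 (0.05), RNR1 (0.12), RNR2 (-0.31), RNR3 (-0.23, adjusted p = 0.564, with the block 0.0438, with pairs averaged 0.0823), RNR4 (-0.11), HUG1 (-0.29) and MAG1 (0.08) did not pass. With camera the NuA4 (adjusted p = 0.0244, adjusted p = 0.22 with an estimated correlation), M/G1 (adjusted p = 0.0244, adjusted p = 0.662 with an estimated correlation) and iron lists (median -0.13, adjusted p = 0.0244, adjusted p = 0.22 with an estimated correlation) passed, although 0 of their members did over all genes with limma and 2, 2 and 0 did adjusted over the list alone. The 5 calls compare with 232 genes at an unadjusted p under 0.05 with 36 up and 47 down with the block, and with 139 calls when the arrays were scaled (36.7% of them higher, against 20.0%). Without replicate 1 or replicate 2 there were 0. ADE2 (0.72, 1.43, 1.77 and 1.44) and SNZ3 (-0.61, -0.54, -0.65 and -0.65) were the genes called in the same direction in all 4 strain comparisons. With the block, AI5_BETA, DSE1, ECM2, EPL1, GPH1, SPT5 and TOS8 were also higher in all 4, and HIS3, DIA3, HXT5 and SNZ2 lower. Of these, ECM2 (adjusted p = 0.0655), EPL1 (adjusted p = 0.0864), TOS8 and HIS3 did not pass in S with MMS when pairs were averaged.

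**Figure D4:**
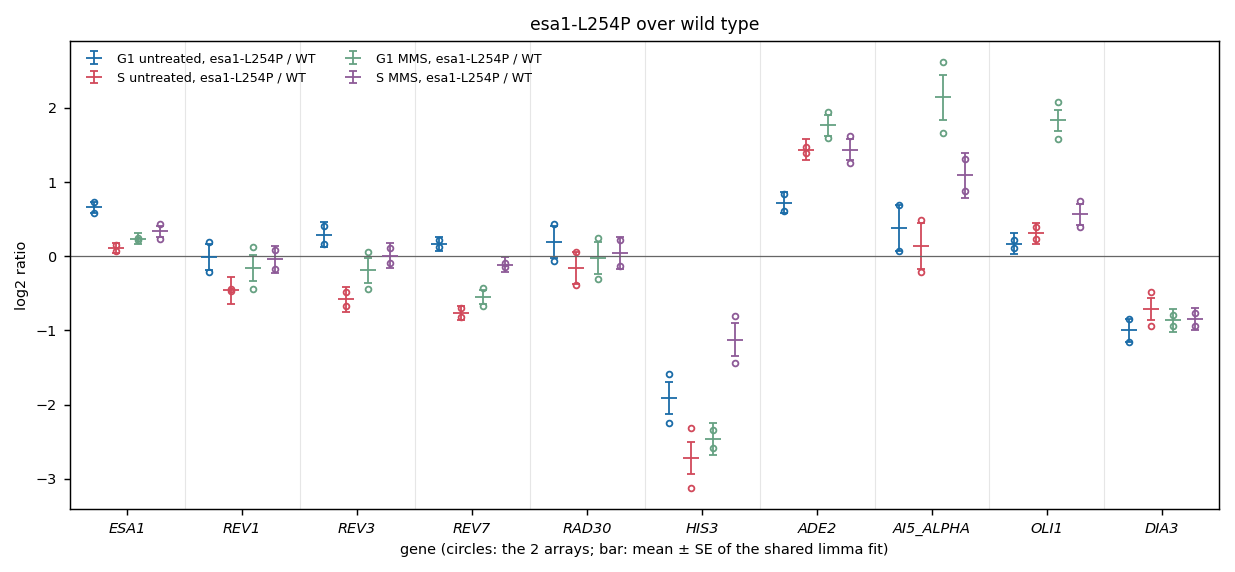
Log2 ratios of esa1-L254P over wild type for ESA1, translesion synthesis genes, HIS3, ADE2, mitochondrial genes and DIA3 in each phase and treatment. Circles are the 2 arrays, bars the mean ± standard error; HIS3 stood at -2.72 in untreated S.

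Whether the MMS response differs between the strains was tested in each phase over 8 arrays. The value is the log2 ratio of MMS over untreated in esa1-L254P minus that in wild type. Here too a difference cannot be assigned to the allele alone. A positive difference can be a larger rise, a smaller fall or a change of sign. In G1 the difference was positive for DHH1 (2.19 ± 0.28), DED1 (2.03 ± 0.22), SPE1 (1.88 ± 0.31), AI5_ALPHA (1.64 ± 0.31), SRO9 (1.62 ± 0.10), OLI1 (1.51 ± 0.14), AI5_BETA (1.48 ± 0.51) and IDP1 (1.48 ± 0.25). It was negative for RPL20B (-1.87 ± 0.62), VMA10 (-1.83 ± 0.27), EGD2 (-1.75 ± 0.63), TIF11 (-1.66 ± 0.44), FYV6 (-1.65 ± 0.07), NOP15 (-1.63 ± 0.19), HMRA1 (-1.62 ± 0.12) and SLF1 (-1.61 ± 0.26). It was negative too for REV7 (-0.70 ± 0.10, adjusted p = 0.000377), REV3 (-0.47 ± 0.17, adjusted p = 0.0481), ESA1 (-0.48 ± 0.07, adjusted p = 0.000516) and MAG1 (-0.50 ± 0.16, adjusted p = 0.0335, with pairs averaged 0.0508), and positive for RNR3 (0.23, adjusted p = 0.0397), which fell in wild type only. RNR1 (0.68), RNR2 (0.53), RNR4 (-0.12), HUG1 (0.09), REV1 (-0.18) and RAD30 (-0.20, adjusted p = 0.477, with the block 0.0165) did not pass. General stress genes had a positive difference in 12 of 30 cases (13 adjusted over the list alone), with ALD3 at 0.92, GSY2 at 0.76, XBP1 at 0.72 and DDR2 at 0.58 against HSP12 (-0.80). With camera the list had adjusted p = 0.00999, and adjusted p = 0.354 with an estimated correlation. M/G1 genes, of which 11 fell in wild type, had a positive difference in 13 of 23 (14 adjusted over the list alone), with MCM3 at 0.83, SCW11 at 0.79, DSE2 at 0.83 and EGT2 at 0.66. For the list, camera gave adjusted p = 0.00999, and adjusted p = 0.354 with an estimated correlation. Excision repair had a negative difference in 11 of 22 cases (12 adjusted over the list alone), with RAD26 at -0.77, RAD27 at -0.56 and NTG2 at -0.47 against RAD16 (0.48). In camera the group had adjusted p = 0.0301, and adjusted p = 0.354 with an estimated correlation. Ribosome biogenesis (17 of 48 lower, 17 adjusted over the list alone, against UTP10 at 0.64, NOC4 at 0.51, ERB1 at 0.28 and RRP12 at 0.27; adjusted p = 0.034, adjusted p = 0.576 with an estimated correlation), ribosomal proteins (1 of 135 lower, 0 adjusted over the list alone, 99 with the block; adjusted p = 0.0102, adjusted p = 0.811 with an estimated correlation) and iron genes (5 of 19 higher, 4 adjusted over the list alone; adjusted p = 0.034, adjusted p = 0.354 with an estimated correlation) also passed. The translesion list did not (adjusted p = 0.221), with ELG1 at -0.73 and SIZ1 at 0.38, nor did the checkpoint list (adjusted p = 0.0816, with the block 0.0375, with the block and an estimated correlation 0.592). In all, 871 genes were higher and 824 lower (1339 and 1235 with the block). Clearly fewer were called from the MMS arrays alone or from the strain arrays alone.

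In S the signs turned for several of these genes. VMA10 (1.35 ± 0.27), HMRA1 (1.13 ± 0.12), YSY6 (1.08 ± 0.17), AI5_ALPHA (1.05 ± 0.31), GSY1 (0.99 ± 0.07), SRP21 (0.99 ± 0.18), NRG2 (0.96 ± 0.12) and SLF1 (0.95 ± 0.26) had a positive difference. SNO1 (-1.27 ± 0.12), GPD2 (-1.18 ± 0.25), RGM1 (-1.08 ± 0.22), PIN3 (-1.06 ± 0.12), FRE4 (-1.03 ± 0.11), TRM5 (-1.02 ± 0.15), BNA2 (-1.02 ± 0.10) and CLN2 (-0.96 ± 0.09) had a negative one. REV7 (0.60 ± 0.10, adjusted p = 0.00271), REV3 (0.62 ± 0.17, adjusted p = 0.0261) and ESA1 (0.28 ± 0.07, adjusted p = 0.0202) had a positive difference. REV1 (0.33, adjusted p = 0.23, with the block 0.0222), RAD30 (0.21, adjusted p = 0.554, with the block 0.0219), RNR2 (-0.83, adjusted p = 0.222, with the block 0.0238), RNR3 (-0.21, adjusted p = 0.0952, with the block 0.00612), RNR4 (-0.46, adjusted p = 0.168, with the block 0.0481) and HUG1 (-0.29, adjusted p = 0.204, with the block 0.046) passed only with the block. Neither RNR1 (-0.18) nor MAG1 (0.23) passed. Iron genes had a negative difference in 9 of 19 cases (11 adjusted over the list alone), with ARN1 at -0.77, TIS11 at -0.85, FIT3 at -0.94 and CCC2 at -0.52. The group as such had adjusted p = 2.29e-05, and adjusted p = 0.0292 with an estimated correlation. With the block and an estimated correlation they did not pass (adjusted p = 0.152). Ribosome biogenesis had a positive difference in 12 of 48 cases (12 adjusted over the list alone, 19 with the block), with EBP2 at 0.56, RRP5 at 0.49, NOP4 at 0.63 and DIP2 at 0.29. Together these genes had adjusted p = 0.0135, and adjusted p = 0.909 with an estimated correlation. In all, 484 genes were higher and 390 lower (879 and 920 with the block). In total, 190 were called from the MMS arrays alone, 381 from the strain arrays alone, and 531 without the second wild-type S array of MMS over untreated.

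Pooled fits over 8 arrays asked which effects hold by phase, strain or treatment. As above, a difference in cell cycle position between treated and untreated S cells may enter the differences of the MMS response by phase. The MMS response was higher in S than in G1 for RNR1 (2.02 ± 0.33, adjusted p = 0.0436), RNR4 (1.33 ± 0.20, adjusted p = 0.033), RNR3 (1.24 ± 0.15, adjusted p = 0.0122), CRH1 (1.16 ± 0.18), CLB6 (1.11 ± 0.13), NDE2 (1.08 ± 0.16), POL12 (1.07 ± 0.12) and POL1 (1.03 ± 0.12). It was lower for SWI5 (-3.08 ± 0.25), HOF1 (-2.46 ± 0.15), HST3 (-2.22 ± 0.14), CLB2 (-1.97 ± 0.16), CDC5 (-1.81 ± 0.17), CLB1 (-1.80 ± 0.21), BUD4 (-1.76 ± 0.17) and CHS2 (-1.63 ± 0.25). With the 2 arrays of each comparison averaged, the calls of RNR4 (adjusted p = 0.332), RNR3 (adjusted p = 0.506), CRH1 (adjusted p = 0.679), CLB6 (adjusted p = 0.837), NDE2 (adjusted p = 0.997), POL12 and POL1 (adjusted p = 0.999 each) were lost, while RNR1 and these 8 lower genes still passed. In that averaged fit the adjusted p followed the size of the change, from 0.999 for POL12 to 9.67e-10 for SWI5. It therefore orders genes by size and is a weak check of each call. HUG1 (0.83, adjusted p = 0.0868, with the block 0.0453) and REV1 (-0.96, adjusted p = 0.0878, with the block 0.0351) passed only with the block and not with pairs averaged (adjusted p = 0.999 each). RNR2 (1.59, adjusted p = 0.12) passed with the block (adjusted p = 0.0471) and with pairs averaged (adjusted p = 0.0464). MAG1 (0.14), ESA1 (-0.25), REV3 (-0.08), REV7 (0.17) and RAD30 (-0.17) did not pass. The CLB2 cluster was lower in 13 of 19 cases (18 adjusted over the list alone; adjusted p = 9.42e-32). G1/S genes were higher in 6 of 31 (17 adjusted over the list alone; adjusted p = 1.34e-17), with MSH6 at 0.99 (adjusted p = 0.999 with pairs averaged), and damage-inducible genes in 3 of 17 (7 adjusted over the list alone, 6 with the block; adjusted p = 1.88e-06). All 3 lists passed with either correlation. With the block and the correlation estimated, G1/S genes passed (adjusted p = 0.0157) and the CLB2 cluster and damage-inducible lists did not (adjusted p = 0.0546 each). In all, 16 genes were higher in S and 19 lower (40 and 42 with the block, 3 and 10 with pairs averaged), with 536 at an unadjusted p under 0.05. Leaving out any of the 8 arrays lowered the count, to 6 without either wild-type G1 array, the second esa1-L254P G1 array or the first wild-type S array, to 7 without the second wild-type S array, to 15 without the first esa1-L254P G1 array, and to 12 and 23 without the first and second esa1-L254P S array.

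The other pooled fits called 0 genes with limma. They had no term for an interaction of phase with strain or with MMS, so such an interaction enters their residual. Their 0 calls therefore do not show that strain leaves the MMS response unchanged. Within a phase that response differed between the strains for 1695 genes in G1 and 874 in S. The MMS response by strain had 93 genes at an unadjusted p under 0.05 (230 with the block), the strain effect by phase 62 (93 with the block) and the strain effect by MMS 62 (100 with the block); with the block and with pairs averaged the calls were 0 as well. AI5_ALPHA (1.34) and OLI1 (0.96) by strain, HXT6 (-1.02) by phase and HXT6 (0.76) by MMS were among the genes with the lowest p and did not pass. With camera several lists passed in each fit at the preset correlation, but no list fixed beforehand passed with an estimated correlation. By strain these were ribosomal proteins (adjusted p = 9.16e-13), G1/S (adjusted p = 7.05e-05, adjusted p = 0.0826 with an estimated correlation), general stress, M/G1, histone and mating genes. For the strain effect by phase they were respiratory (adjusted p = 0.000138, adjusted p = 0.902 with an estimated correlation), iron, general stress and G1/S genes. For the strain effect by MMS the lowest were general stress genes (adjusted p = 1.62e-05, adjusted p = 0.545 with an estimated correlation). G1/S genes (adjusted p = 2.95e-05), ribosomal proteins (adjusted p = 0.000751) and further lists passed there too.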

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

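Of the tests in this part, the differences between phases within 1 strain or treatment, the length correction, the check of HIS3 against exchanged strain labels and the lists of other HIS and other ADE genes were chosen only after the results had been seen.

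Differences between groups were the results singled out for a closer look. The MMS response differed between strains for 1695 genes in G1 and 874 in S, and between phases, over both strains, for 35. The wild-type G1 response correlated across genes at 0.610 with the untreated G1 strain effect, and both have untreated wild-type G1 cells as the denominator. A deviation of that RNA would enter both and could not be told apart here from an effect of the allele. Within wild type the response differed between S and G1 for 1313 genes (2121 with the replicate as a block), with RNR1 higher in S by 2.53 ± 0.45 (adjusted p = 0.00217), RNR3 by 1.49 ± 0.11 (adjusted p = 4.56e-05) and HUG1 by 1.05 (adjusted p = 0.00416), and with CLB2 lower by 2.17 and SWI5 by 3.51. Within esa1-L254P it differed for 389 genes (1099 with the block), with RNR3 higher in S by 0.99 (adjusted p = 0.00103), CLB2 lower by 1.78, SWI5 lower by 2.65, and RNR1 not passing (1.51, adjusted p = 0.0658, with the block 0.0261). The strain effect of untreated cells differed between phases for 1380 genes (2248 with the block), 630 higher and 750 lower in S, and that of MMS-treated cells for 9 (432 with the block).

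For the MMS response by phase, chance could not be excluded by other splits of the 8 arrays: the real count was 35 and the highest other 232. The split that gave 232 followed the dye, and the real count was 82 with the block and 13 with the arrays of each comparison averaged. Of the 2 splits tested that kept the arrays of each comparison together, the real one called 35 and the one that grouped wild-type G1 with esa1-L254P S called 191, or 690 with the block, several times the real count. The wild-type G1 response correlated across genes at 0.339 with wild-type S and at 0.411 with esa1-L254P G1. Between phases in esa1-L254P the correlation was 0.682, and between strains in S 0.786. Whether this accounts for that split was not tested. In all, 3 of 34 splits called as many genes. For the MMS response by strain and the strain effects by phase and by MMS, the real count was 0 with limma (unadjusted 93, 62 and 62), so that all 34 splits were as large by construction and the splits say nothing about chance. The highest other counts were 758, 335 and 861, and the splits by dye called 246, 335 and 351.

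The untreated strain effect was opposite in G1 and S across genes (r = -0.633). A trend with coding length ran in opposite directions as well (rank correlation -0.264 in G1 and 0.099 in S), but after its removal the correlation was still -0.623, which argues against length as the source. The length trend was uneven between arrays, at -0.336 and -0.043 in G1 and at -0.028 and 0.213 in S. It was largest for the strain difference of the MMS response in G1 (0.328). Exchanged strain labels in 1 phase would have turned HIS3, yet the highest HIS3 value among the 4 untreated strain arrays was -1.58, which argues against it. A strain effect that depends on the phase was left open. The pooled test called 0 genes with limma (unadjusted 62, 0 with the block), but it had no term for an interaction of phase with MMS. Its 0 calls therefore cannot decide the question. Each RNA may come from 1 culture, in which case a difference of that culture, in cell cycle position or growth, would enter every array that used it.

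HIS3 was lower and ADE2 higher in esa1-L254P, with mean strain effects of -2.05 and 1.34 that ranked first and second among all genes. Both genes are auxotrophic markers of W303, and a difference in marker genotype predicts that the rest of each pathway stays near 0. Over the 4 strain comparisons the median of 6 other HIS genes was 0.217 and that of 9 other ADE genes 0.117, which for HIS3 is consistent with a difference in marker genotype and argues against a fall of the whole pathway. For ADE2 it was left open, as the other ADE genes went opposite ways, with medians of -0.152 in untreated G1 and -0.048 in S with MMS, but 0.280 in untreated S (adjusted p = 0.0409, with the block 0.082, adjusted p = 0.113 with an estimated correlation) and 0.337 in G1 with MMS (adjusted p = 0.00577, adjusted p = 0.0588 with an estimated correlation). The genotypes at these loci were not analysed here.

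The 4 comparisons of a phase form a square, so that the strain difference of the MMS response can be had from the MMS arrays or from the strain arrays. Both ways correlated across genes at 0.929 in G1 and 0.871 in S, and the spread of their gap was 0.704 and 0.635 of that expected from the dye-swap spread, with 0 genes called for the gap with limma. This may reflect 4 RNA extracts per phase shared by all its arrays; then biological variation between cultures is not measured by the standard errors.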

How the results depend on the processing

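The length correction with the block was the alternative chosen after the data were seen. The cause of the changes below was not tested. Totals follow the order MMS in wild-type G1 and S, MMS in esa1-L254P G1 and S, strain effect in untreated G1 and S, strain effect with MMS in G1 and S, strain difference of the MMS response in G1 and S, and MMS response by phase, for which the report gives 1466, 1560, 1108, 1348, 872, 846, 399, 5, 1695, 874 and 35. With the replicate as a block they were 2292, 2376, 2090, 2268, 1780, 1609, 1203, 83, 2574, 1799 and 82, and with the arrays of each comparison averaged 2819, 2852, 2592, 2746, 2358, 2165, 1741, 123, 2882, 2156 and 13. Without centring the strain effect with MMS in S had 3 calls. Scaled arrays gave 881 and 962 for wild-type G1 and S, 839 for esa1-L254P S and 139 for the strain effect with MMS in S, whose share of higher genes was 20.0% in the report, 33.3% without centring and 36.7% when scaled. The block with the length correction gave 2257 for wild-type G1, 1926 and 2274 for esa1-L254P G1 and S, 1638, 1537, 1105 and 58 for the strain effects and 1700 for the strain difference in S. It also turned DDR2 in the untreated G1 strain effect (-0.046) and CYC7 in the strain difference of G1 (0.106). The 8 arrays of a phase gave 499, 559, 55 and 0 for the strain effects and 554 for the strain difference in S. Each spot on its own gave 947, 1037, 627, 813, 426, 408, 124 and 2. The strain difference from the MMS arrays alone had 967 genes in G1 and 190 in S, and from the strain arrays alone 1064 and 381. Leaving out 1 array gave 592 to 873, 728 to 803, 407 to 549, 682 to 821, 293 to 3.0e+02 (175 up and 128 down), 154 to 205, 65 to 154, 0 to 0, 1356 to 1585, 531 to 768 and 6 to 23, and 0 for the other pooled fits. The strain difference in S moved by over 1.5 times only without the second wild-type S array (531). Of 322 list results, 76 passed only with the preset correlation; the block gained 17 and lost 3. Of 1598 named gene values, the block made 168 pass and changed no other call, pairs averaged made 246 pass and 14 fail, scaling 27 and 133, no centring 16 and 19, and the block with the length correction 150 and 31. The 8 arrays of a phase made 13 pass and 172 fail. From the MMS arrays alone 89 values failed, and from the strain arrays alone 1 passed and 65 failed. Over all runs without 1 array, 30 values passed and 886 failed. No filter removed a gene, as no value was missing.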

Other observations

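Genes of ergosterol biosynthesis, a list added after the values were seen, had members that fell with MMS in each strain and phase, although with an estimated correlation the list passed in none. In wild-type G1 16 of 23 fell at a median of -1.10 (adjusted p = 1.72e-06, adjusted p = 0.319 with an estimated correlation), with ERG3 at -1.94 ± 0.52, ERG11 at -1.88 ± 0.50 and ERG5 at -1.80 ± 0.39. In wild-type S 7 fell, or 14 with the replicate as a block (adjusted p = 0.0428, adjusted p = 0.455 with an estimated correlation). In esa1-L254P 12 fell and 1 rose in G1 (adjusted p = 1.34e-05, adjusted p = 0.283 with an estimated correlation), and 9 fell in S (14 with the block; adjusted p = 0.000193, adjusted p = 0.329 with an estimated correlation).

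Markers of other cell states moved as well, though their list passed in none of the 8 comparisons. SAG1 fell with MMS in wild-type G1 (-1.07, adjusted p = 1.64e-05) and rose in wild-type S (0.45, adjusted p = 0.00112), while SPS4 fell in S in both strains (-1.57 in wild type and -1.41 in esa1-L254P). The meiotic genes NDT80 (0.57), HOP1 (0.59) and DMC1 (0.56) rose in wild-type G1. In untreated esa1-L254P over wild type, 5 of 18 list members were higher and 1 lower in G1, against 2 higher and 7 lower in S. Of the mating response, KAR4 rose (0.85) and MSG5 fell (-0.83) with MMS in wild-type G1, and FAR1 (-0.75) and STE12 (-0.66) fell in S; the list passed in neither (adjusted p = 0.403 and 0.988). In the strain effect with MMS, other ADE genes had 1 of 9 higher in G1 (3 with the block; adjusted p = 0.00577, adjusted p = 0.0588 with an estimated correlation) and mitochondrially encoded genes 0 of 17 in S with limma (5 with the block; adjusted p = 3.95e-05, adjusted p = 0.644 with an estimated correlation). Other HIS genes had 0 of 6 called with limma in either phase (2 higher in G1 with the block). The list of W303 marker genes did not pass with MMS in wild-type G1 (0 of 6 called with limma, adjusted p = 0.662 with camera) or S (HIS3 and ADE2 up, HIS3 not with pairs averaged, at adjusted p = 0.261; list adjusted p = 0.206).

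Hypotheses that these data leave open can be tested. If the opposite strain effects of untreated G1 and S cells (r = -0.633, and -0.623 without the length trend) reflect a strain effect that depends on the phase, independent cultures of both strains would show it again, with VMA10, SPO12 and FYV6 as first genes to measure. If the lower REV3 and REV7 in untreated esa1-L254P S cells lowers polymerase zeta, its protein level in untreated S cells would fall with it. With MMS in S neither gene passed between the strains (REV7 at -0.11), and the strain difference of the response was positive for both. Neither mutation rate nor protein level was measured, so what these transcripts mean for mutation induced by MMS was left open. Genotyping HIS3 and ADE2 in both strains would settle whether these 2 genes differ by marker. The higher OLI1 and AI5_ALPHA in MMS-treated esa1-L254P G1 cells could be a change of mitochondrial RNA or of mitochondrial DNA content. A measurement of DNA copy number would test the DNA content only.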
